A study of Mus musculus with 4 samples.

How the data were processed

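Messenger RNA profiles came from 4 stranded mRNA libraries of macrophages grown with M-CSF from the bone marrow of C57BL/6 mice aged 7 weeks. The libraries were wild type (WT) without LPS, WT with LPS, Sema6D-/- without LPS and Sema6D-/- with LPS, 1 library per group. LPS (lipopolysaccharide, a bacterial cell wall component that activates macrophages) was given at 100 ng/ml for 4 h per the labels. The treatment text of every sample mentions LPS, and the library titles separate the groups, so "non" in a title was read as not stimulated. The labels name different RNA extraction reagents in different places, which was left unresolved.

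The deposited values were FPKM (fragments per kilobase of transcript, scaled to library depth), 1 value per RefSeq transcript and library. Per the submitters' processing notes the tools were TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cuffnorm 2.2.1 on the mouse build mm9; their order, options and annotation version were not stated, nor was the scaling used between libraries. Each table held 34487 transcripts. Gene names came from the GRCm38 RefSeq table for 34163 transcripts and from the GENCODE vM21 annotation for 187, and 137 unmatched transcripts were left out. Only names, biotypes, gene order and transcript sequences were taken from that reference. Transcripts were summed per gene, which gave 24235 genes, 5540 of them with several transcripts. The plan had been to leave out symbols that occurred more than 1 time, on the assumption of gene-level tables. It was changed because that would have dropped Sema6d, Pparg, Cd36 and Tnf, and the result for genes with 1 transcript is given as an alternative.

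Ratios were log2((FPKM + 1)/(FPKM + 1)), which understates ratios of genes with low values. Where unstimulated values were low and unequal between genotypes, the added 1 can enlarge or turn the difference of the LPS responses. A gene entered a comparison at 1 FPKM or more in at least 1 of the libraries compared, and counts used a size rule of 2-fold. The comparisons were LPS against no LPS in each genotype, Sema6D-/- against WT without and with LPS, and the difference of the LPS responses (Sema6D-/- minus WT). The last of these, and the correlation of the responses across genes, used the 10680 genes at 1 FPKM or more in any library, of which 10291 were protein-coding and 123 small RNAs. Genes apart the same way in both genotype comparisons were counted beside the number expected of independent lists. With 1 library per group there was no replicate to measure variation between libraries, so no test across libraries was run, and no p-value, SD or SE across libraries was computed. An additive model of genotype and LPS would have had to take the difference of the responses as error, and it was not fitted.

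The 27 gene lists were inflammatory cytokines and chemokines, NF-kB pathway and feedback, interferon-stimulated genes, alternative activation, PPARg/RXR and lipid uptake, LXR targets, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, glycolysis, oxidative phosphorylation, mTOR signalling, semaphorins and plexins, ATF4 and unfolded protein response, NRF2 targets, lysosome, cell cycle, immediate early genes, macrophage identity, MHC class II and dendritic cells, neutrophils, monocytes and progenitors, lymphocytes, erythroid and megakaryocyte cells, mast cells and basophils, stromal cells, and sex-linked genes. Members at 1 FPKM or more in any library counted as measured. The median log2 ratio of a list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart below percentile 2.5 or above 97.5. These percentiles describe these libraries only. Some genes sit in more than 1 list, among them Chil3, Il10, Apoe and Slc7a11. Gapdh, Eno1 and Hmgcs1 were below 1 FPKM in every library and are not measured members.

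Comparisons, size rule, filter, gene lists and the rule for named genes were fixed before the data were examined. The rule named 17 genes in every comparison where measured, the 10 highest and 10 lowest ratios per comparison at 5 FPKM or more in at least 1 library, and up to 4 members per list. Small RNAs filled most of these places. They took 8 of the 10 highest and 10 of the 10 lowest for LPS in WT, 5 and 10 for LPS in Sema6D-/-, 10 and 10 for genotype without LPS, 9 and 10 for genotype with LPS, 10 and 10 for the difference of responses, and 0 and 5 for genes apart in both states, where the long non-coding Xist took another of the lowest places. A ranking of the 15 highest and 15 lowest protein-coding genes was therefore added after the values were seen, and names from it are used below.

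Sequencing depth was recovered from the steps of low FPKM values. FPKM times effective transcript length fell on whole multiples of 1 step, within a tolerance of 0.1, for 71.9 to 73.8% of low values in the 4 libraries, against 20% by chance. The estimated depths were 23.5 M fragments for WT without LPS, 22.1 M for WT with LPS, 17.2 M for Sema6D-/- without LPS and 21.4 M for Sema6D-/- with LPS. On a transcript of 2 kb, 1 FPKM stood for 55.3, 36.1, 40.0 and 29.8 fragments in the same order, and a floor of 3 fragments stood for 0.0543, 0.0830, 0.0750 and 0.101 FPKM. Exact binomial 95% intervals of ratios between libraries were computed from these fragment numbers without the added 1. The intervals cover counting error only, not differences between animals or cultures. FPKM per fragment and kilobase times the estimated M fragments gave 0.768 and 1.10 in WT without and with LPS and 0.778 and 1.31 in Sema6D-/-. Division by mapped fragments alone leaves this product at 1 or below, so the deposited values carry a further scaling between libraries. The summed FPKM differed as well, at 370066 and 534692 in WT without and with LPS and 371243 and 628278 in Sema6D-/-.

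The calls were tested on simulated data with fragments redrawn at the estimated depths, so with counting error only. Variation between animals or cultures was not simulated. The shares below are therefore not error rates of the calls in real libraries. Of genes changed 3-fold in the comparison without LPS, 44 of 47 higher (93.6%) and 40 of 48 lower (83.3%) passed 2-fold. With LPS, 46 of 48 (95.8%) and 36 of 45 (80.0%) passed. Genes changed 1.5-fold passed in 0 of 47 and 1 of 48 cases without LPS and in 0 of 49 and 0 of 47 with LPS. Unchanged genes passed in 2 of 9851 and 2 of 9640 cases. Of 9318 protein-coding genes with counting error alone, 0 passed the same way in both states. Of 200 random lists of 20 genes 6.5% stood apart, and 50 of 50 lists moved 1.5-fold did. The LPS comparisons were not simulated.

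Alternatives were pseudocounts of 0.1 and 5 FPKM, rescaling each library to a common total, centring each pair on the median or on the 30% trimmed mean of genes at 5 FPKM or more, no filter or a filter at 5 FPKM, size rules of 1.5-fold and 4-fold, random lists without matching, list means, unmeasured list members kept, and genes with 1 transcript only. Restriction to protein-coding genes and leaving out X and Y genes were added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.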

Results

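Macrophages grown from mouse bone marrow were profiled by mRNA sequencing in 4 libraries, WT and labelled Sema6D-/-, each without LPS and after 4 h with LPS. Every group was a single library, so no difference below has a replicate check, and all values describe these 4 libraries. Estimated depth was 17.2 to 23.5 M fragments, and 9682 to 10057 genes per library reached 1 FPKM. A log2 ratio followed by square brackets was computed without the added 1, and the brackets hold its 95% counting interval. All other log2 ratios include the added 1.

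Sema6d, which encodes a membrane-bound semaphorin, was low in all 4 libraries and was not lower in those labelled Sema6D-/-. It measured 0.304 FPKM (56 fragments) in WT without LPS and 0.219 (20 fragments) in WT with LPS. In the libraries labelled Sema6D-/- it measured 0.563 (77 fragments) and 0.592 (59 fragments). The log2 ratio of the library labelled Sema6D-/- to WT was 0.89 [0.38, 1.42] without LPS and 1.44 [0.71, 2.27] with LPS, the opposite direction to the label. The transcript variants that held the signal also differed by genotype. In WT they were 3 variants (0.239 and 0.0656 FPKM without LPS, 0.168 and 0.0501 with LPS), each at 0.00662 FPKM or less in the libraries labelled Sema6D-/-. There they were 2 other variants (0.451 and 0.105 FPKM without LPS, 0.590 with LPS), each at 1.05e-05 FPKM or less in WT. The leading variant also differed between states within each genotype, and assignment to variants rested on 20 to 77 fragments. The labels do not say which part of the gene was deleted, and values per transcript do not show coverage of single exons. An exchange of the genotype labels would turn the sign of every genotype ratio below, and neither the totals nor the variants show which libraries carry the deletion. LPS ratios of Sema6d were -0.48 [-1.31, 0.27] in WT and 0.07 [-0.44, 0.58] in the libraries labelled Sema6D-/-, so no difference was detectable at this depth.

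The genotypes also differed in sex-linked genes. Xist, the RNA made from the inactive X chromosome of female cells, measured 22.3 and 21.4 FPKM in the WT libraries and 0.0333 and 0.0306 in those labelled Sema6D-/-. The Y-linked genes Eif2s3y (33.5 and 50.4 FPKM) and Ddx3y (13.2 and 16.6 FPKM) were found in the libraries labelled Sema6D-/-, against at most 0.0207 FPKM in WT. Kdm5d (3.40 and 3.36 FPKM) and Uty (4.60 and 3.79 FPKM) followed the same split. Of the 8 measured genes in the sex-linked list 4 were higher and 1 lower in both genotype comparisons (medians 0.89 and 0.93), while LPS medians were -0.01 in WT and 0.13 in the other genotype. Every genotype comparison below carries this difference.

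In WT cells the library with LPS held much higher levels of inflammatory and interferon-driven transcripts. Cxcl10, an interferon-induced chemokine, measured 30.5 FPKM without LPS and 6696 with LPS (log2 ratio 7.73). Tnf, a central inflammatory cytokine, went from 31.5 to 357 FPKM (3.50 [3.42, 3.58]) and Il6 from 0.759 to 169 (7.80 [7.20, 8.48]). Il1b measured 7.88 and 177 FPKM, Nos2, the inducible nitric oxide synthase, 0.598 and 128, and Il12b, the p40 subunit shared by IL-12 and IL-23, 0.253 and 26.0. Il10, an anti-inflammatory cytokine, was also higher with LPS, at 96.7 against 13.5 FPKM (2.75). Ch25h, which makes an oxysterol with antiviral activity, had a log2 ratio of 7.33, and Cd69, an early activation marker, 7.25.

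Of 29 measured inflammatory cytokines and chemokines, 26 were at least 2-fold higher with LPS in WT and 0 were lower, with a median log2 ratio of 3.46. Il27 (6.66) and Ccl5 (5.95) were among them. In the NF-kB list 22 of 24 members were higher and 0 lower (median 2.18), led by the co-stimulatory receptor Cd40 (4.94) and the feedback inhibitor Socs3 (4.47). Of 40 interferon-stimulated genes 38 were higher and 0 lower (median 3.71), among them the GTPase Gbp5 (6.98) and the antiviral enzymes Cmpk2 (6.13) and Rsad2 (6.10). All 3 medians lay above all 10000 random lists. Lower with LPS were Sesn1, a stress-induced inhibitor of mTORC1 (41.8 to 2.38 FPKM, -3.66), Cebpa, a myeloid transcription factor (-3.00), and Cxcr4, a chemokine receptor (-2.55).

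Lipid genes of WT cells were mixed. Pparg, the lipid-sensing nuclear receptor, was lower with LPS at 7.11 against 16.2 FPKM (-1.19 [-1.39, -1.0]), as were its partner Rxra (-2.0) and Angptl4, an inhibitor of lipoprotein lipase (-2.49). The fatty acid transporter Cd36 had a ratio of -0.08, the fatty acid carrier Fabp4 0.76, and Acsl1, which activates long-chain fatty acids, 2.67. The PPARg list held 2 higher and 4 lower of 25 measured members, with a median of -0.08 at percentile 0.545. The mannose receptor Mrc1 (0.32), which measured -0.20 after rescaling to a common total, and the chitinase-like Chil3 (0.71) were below the size rule, as were Plxna1 (-0.12), a class A plexin receptor, and Mtor (0.18). The ratio of Mtor turned negative under the same rescaling. Arg1, Plxna4 and Sema6d stayed below 1 FPKM and Retnla was listed at 0 in all 4 libraries.

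In total 1114 of 10375 genes were at least 2-fold higher and 503 lower with LPS in WT, and among protein-coding genes 1045 of 10036 were higher and 444 lower. The split depended on scaling, since after rescaling each library to a common total 713 genes were higher and 1502 lower. The median log2 ratio of the 6110 genes at 5 FPKM or more in every library was 0.11 in WT and 0.15 in the libraries labelled Sema6D-/-, and the rescaling moved these responses by -0.51 and -0.72.

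The library labelled Sema6D-/- with LPS held even higher levels of many cytokines over its own unstimulated library. Il6 went from 1.28 to 732 FPKM (9.15 [8.61, 9.76]), Tnf from 54.2 to 1794 (5.05 [4.98, 5.12]), Il1b from 26.1 to 1110.3 (5.36) and Nos2 from 1.98 to 449 (7.24). Il12b measured 1.49 and 78.3 FPKM, and Il10 5.26 and 39.1. Il27 (7.6), Il1a (7.52) and Cxcl9 (6.47), a chemokine induced by interferon gamma, were also far higher. Inflammatory cytokines and chemokines were higher for 28 of 29 members (median 4.62), NF-kB genes for 23 of 24 (2.32) and interferon-stimulated genes for 39 of 40 (3.10), with 0 lower in each and each median above all random lists. Immediate early genes also stood apart here (6 higher, 1 lower of 19, median 0.68, percentile 99.4), on a median that became 0.05 after rescaling to a common total, with Dusp2, a phosphatase of MAP kinases (3.90), Egr1 (2.34) and Klf6 (2.31).

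Among protein-coding genes the lowest LPS ratios in the libraries labelled Sema6D-/- were those of Cd300lb, an activating myeloid receptor (79.6 to 2.27 FPKM, -4.62), Cxcr4 (-4.41), Sesn1 (-4.17) and Zfp36l2, which promotes mRNA decay (-3.98). Tfeb, a transcription factor for lysosomal genes, had -3.22. Pparg measured 5.66 and 2.81 FPKM (-1.01 [-1.38, -0.66]), Rxra had -2.61 and Fabp4 1.53. Cd36 had 0.31, which became -0.42 after rescaling to a common total, as Mrc1 went from 0.38 to -0.33 and Chil3 from 0.71 to -0.00. Plxna1 had -0.50 and Mtor 0.12, which turned negative under the same rescaling. Of 10398 genes 1453 were at least 2-fold higher and 916 lower, and of 10085 protein-coding genes 1388 were higher and 850 lower. This split too depended on scaling, with 745 higher and 3008 lower after rescaling to a common total, 1245 and 1233 after centring on the median, and 1243 and 1235 on the trimmed mean.

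**Figure D1:**
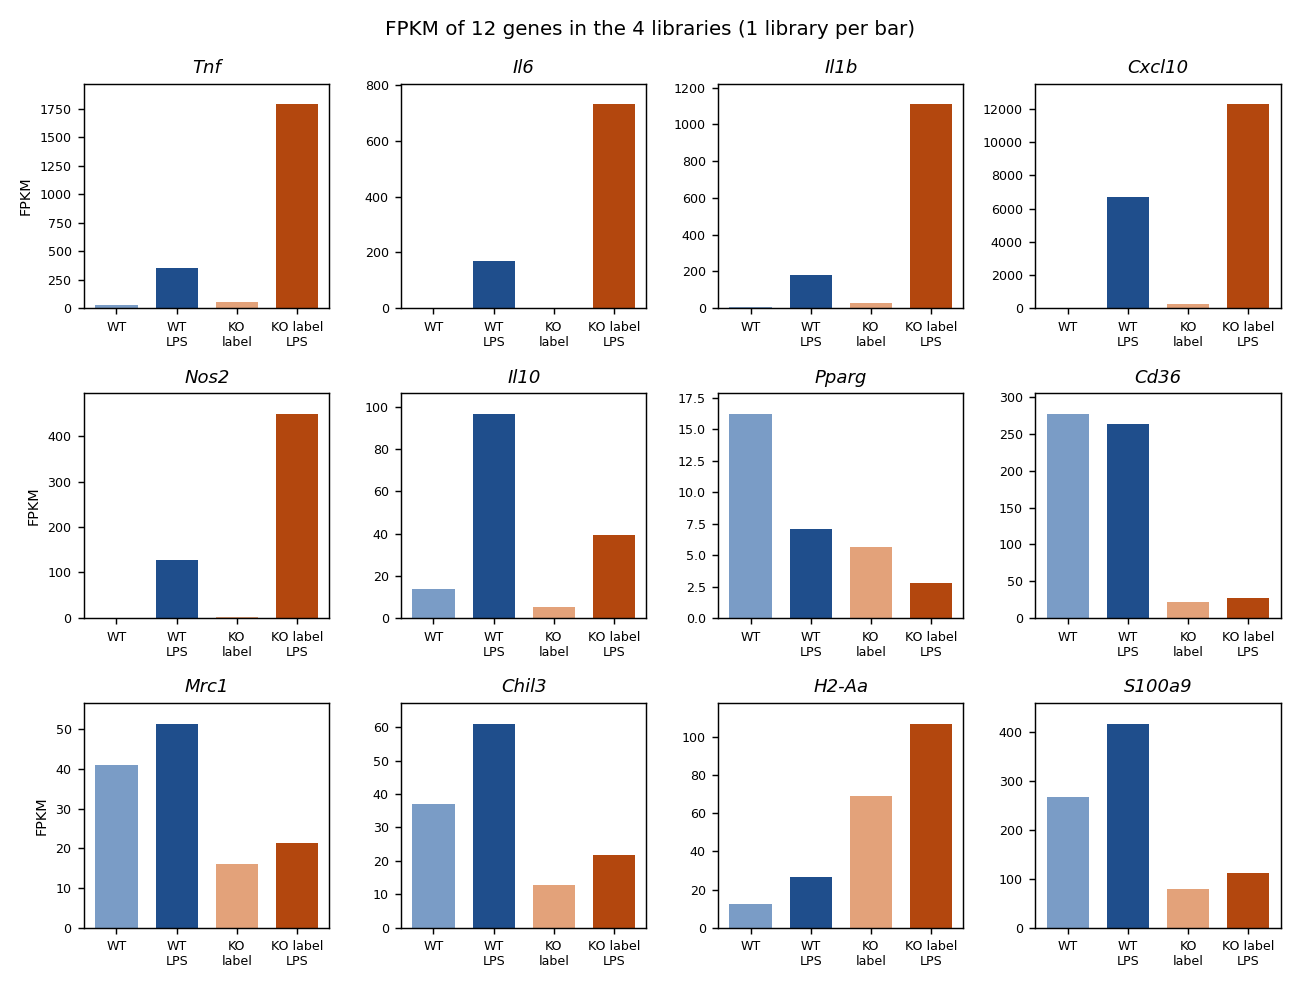
FPKM of 12 genes (1 panel each, axes from 0) in the 4 libraries, 1 bar per library and no error bars because each group was 1 library. Tnf reached 357 FPKM in WT with LPS and 1794 in the library labelled Sema6D-/- with LPS, while Cd36 stood at 277 and 263 FPKM in WT against 22.1 and 27.6 in the libraries labelled Sema6D-/-.

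Further lists stood apart in the LPS responses. The PPARg list lay low again in the libraries labelled Sema6D-/- (4 higher, 3 lower of 25, median -0.12). Against random lists not matched on expression, the LPS medians of the PPARg list and NRF2 targets in both genotypes and of lysosome genes in WT did not stand apart. The cell cycle list had a median of -0.26 in WT (1 higher, 1 lower and 33 between of 35, percentile 0.580) and of -0.25 in the libraries labelled Sema6D-/- (2 higher, 3 lower), which did not stand apart, nor did the mean in WT (-0.18). NRF2 targets, antioxidant genes, lay below random lists with medians near 0 of 0.01 and 0.03, which became -0.48 and -0.68 after rescaling to a common total and -0.10 and -0.12 after centring on the median. The cystine transporter Slc7a11 (1.94 and 3.06) and Osgin1 (-1.97 and -2.13) showed the spread within that list. Lysosome genes had medians of 0.11 in WT, which stood apart and became -0.42 and -0.01 under the same rescalings, and 0.20. MHC class II and dendritic cell markers stood apart with medians of 0.71 in WT and 0.68 in the libraries labelled Sema6D-/-, the latter -0.07 after rescaling to a common total, and included Cd83 (2.16 and 3.35) and Cd86 (1.39 and 2.12), both activation markers.

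By their medians the metabolic lists did not stand apart with LPS in either genotype. By the mean, LXR targets (-0.15 and -0.31) and mTOR signalling (-0.26 and -0.28) stood apart in both genotypes. Oxidative phosphorylation did so in WT (mean 0.18). Medians in WT and in the libraries labelled Sema6D-/- were 0.01 and -0.15 for fatty acid oxidation, -0.03 and -0.09 for fatty acid synthesis, -0.00 and -0.03 for cholesterol synthesis, 0.14 and 0.34 for glycolysis, 0.17 and 0.21 for oxidative phosphorylation, 0.01 and -0.17 for mTOR signalling and 0.06 and 0.06 for LXR targets. Glycolysis included Pfkfb3, which makes an activator of phosphofructokinase (1.94 and 2.31), and Hif1a (1.31 and 1.34), and its medians became -0.38 and -0.37 after rescaling to a common total. Neither semaphorins and plexins (-0.08 and -0.01), the ATF4 list (0.24 and 0.17), alternative activation (0.29 and 0.38), macrophage identity (0.32 and 0.34) nor immediate early genes in WT (0.30) stood apart by the median. The last 3 of these medians did stand apart against random lists not matched on expression. By the mean, macrophage identity stood apart in both genotypes (0.12 and 0.0912), and alternative activation in the libraries labelled Sema6D-/- (0.76). Means and medians differed in sign for LXR targets (means -0.15 and -0.31), cholesterol synthesis (means 0.04 and 0.01) and semaphorins (means 0.12 and 0.0024). In WT they also did for mTOR signalling (mean -0.26) and fatty acid oxidation (mean -0.03). Rescaling to a common total turned the sign of the medians for alternative activation (-0.18 and -0.23), LXR targets (-0.39 and -0.66), oxidative phosphorylation (-0.35 and -0.53), the ATF4 list (-0.27 and -0.42), macrophage identity (-0.20 and -0.42) and immediate early genes in WT (-0.18), and that for lysosome genes in the libraries labelled Sema6D-/- (-0.53). The WT medians of fatty acid oxidation and mTOR signalling also turned negative.

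The responses to LPS were similar in rank across genes. Pearson's r was 0.77 and Spearman's rho 0.89 across 10680 genes, which are not independent replicates, and 0.93 and 0.91 across protein-coding genes. At the size rule 994 genes were higher in both genotypes, 402 lower in both and 11 opposite, none of the 11 protein-coding. Of 1275 genes with a mean response of at least 2-fold up, 868 (68.1%) had the larger response in the libraries labelled Sema6D-/- on the deposited scale, with median log2 ratios of 1.53 in WT and 1.81 there. The share was 64.4% of 1099 genes after centring on the median and 48.75% of 720 after rescaling to a common total, so the larger induction was not kept on every scale. Of 675 genes with a mean response of at least 2-fold down, 563 (83.4%) had the larger response there, with medians of -1.14 and -1.47, and the share was 86.1% of 920 and 89.9% of 2194 genes under the same rescalings.

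Cytokines and interferon-stimulated genes parted in the difference of the responses (libraries labelled Sema6D-/- minus WT). With the added 1, 15 of 29 cytokines and chemokines were at least 2-fold more induced in the libraries labelled Sema6D-/- and 0 less. Their median difference was 1.01, above all random lists. Some of the 15 with low unstimulated values, such as Il1a and F3, would not pass without the added 1. Ccl2, Ccl3, Ccl4 and Ccl7, also among the 15, were lower without LPS in the library labelled Sema6D-/- (-1.37, -0.41, -0.57 and -2.31). With LPS their ratios to WT were 0.15, 0.95, 0.51 and -0.92. Others, such as Tnf (0.76) and Il1b (1.61), were higher there without LPS. Ptgs2, the inducible cyclooxygenase (2.33), Il1a (2.31), Il12a, the p35 subunit of IL-12 (2.06), and the neutrophil chemokine Cxcl1 (1.94) led the list. Il6 had 1.73, Tnf 1.56, Nos2 0.90 and Il12b 0.56. Without the added 1 the responses of Il1a and Nos2 were close to equal in the genotypes. That of Il12b was then smaller in the libraries labelled Sema6D-/-. Il1a measured 0.146 and 41.4 FPKM in WT and 1.21 and 403 there. Nos2 measured 0.598 and 128 in WT and 1.98 and 449 there, and Il12b 0.253 and 26.0 and 1.49 and 78.3. Interferon-stimulated genes had a median of -0.56, below all random lists, with 1 of 40 higher (Cxcl9, 1.77) and 7 lower. Cxcl9 measured 0.168 and 29.3 FPKM in WT and 0.891 and 166 in the libraries labelled Sema6D-/-, so nearly all of its difference came from the added 1. The 7 lower genes included Cxcl10 (-2.21), Ifit3 (-1.25) and Gbp2 (-1.21), and these were already higher without LPS in the library labelled Sema6D-/-. Immediate early genes (0.45, above all random lists; Egr1 1.36, Dusp2 1.04) and glycolysis (0.20, percentile 99.3; Pfkm 0.77) stood apart too, and glycolysis became -0.02 after rescaling to a common total. Neither stood apart by its mean (0.31 and 0.20).

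Among protein-coding genes the response was also larger for Tagap1 (3.14), Ptx3, a soluble pattern recognition protein (2.56), and the inflammasome gene Nlrc4 (2.26). Ifi208 (-3.37) measured 5.72 and 151 FPKM in WT and 0.0480 and 1.30 in the libraries labelled Sema6D-/-, so its difference came from the added 1. Gpr84 (-1.79) and Clec4e (-1.71) were higher with LPS in both genotypes and less so in the libraries labelled Sema6D-/-. Cd300lb (-2.14), Cx3cr1, the fractalkine receptor (-2.08), and Cxcr4 (-1.86) were lower with LPS in both and more so there. Il10 (-0.07), Pparg (0.28), Cd36 (0.38), Fabp4 (0.77), Mrc1 (0.06), Chil3 (0.00), Plxna1 (-0.38) and Mtor (-0.06) were below the size rule. The remaining metabolic and signalling lists did not stand apart, with medians of 0.09 for NF-kB, 0.01 for alternative activation, -0.04 for PPARg, -0.06 for LXR, -0.07 for fatty acid oxidation, -0.10 for fatty acid synthesis, 0.02 for cholesterol synthesis, 0.06 for oxidative phosphorylation, -0.05 for mTOR, -0.07 for semaphorins, 0.11 for ATF4, -0.02 for NRF2, 0.07 for lysosome and 0.01 for cell cycle. Means had the other sign for PPARg (0.02), NRF2 (0.09) and cholesterol synthesis (-0.03). In all 195 of 10680 genes had a difference of at least 2-fold up and 134 down (140 and 79 of 10291 protein-coding genes). The split turned to 123 and 222 after rescaling to a common total, which moved the differences by -0.22 and so turned the sign of the small positive list medians.

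Without LPS the library labelled Sema6D-/- had lower medians than WT for the PPARg and alternative-activation lists and higher medians for interferon-stimulated and antigen-presentation genes. Cd36 measured 22.1 against 277 FPKM (-3.65 [-3.73, -3.57]), Pparg 5.66 against 16.2 (-1.52 [-1.73, -1.32]), Mrc1 16.1 against 41.0 (-1.35 [-1.43, -1.28]), Chil3 12.9 against 37.0 (-1.52 [-1.69, -1.36]) and Il10 5.26 against 13.5 (-1.36 [-1.66, -1.08]). Higher were Cxcl10 at 267 against 30.5 FPKM (3.13 [3.02, 3.23]), the interferon-induced Xaf1 at 123 against 15.3 (3.01 [2.91, 3.11]) and H2-Aa, an MHC class II chain, at 69.2 against 12.5 (2.47 [2.30, 2.64]). The same comparison carries the sex-linked split. In it 9 of 19 measured neutrophil markers were at least 2-fold lower and 0 higher (median -1.0, below all random lists). The calprotectin genes S100a8 (409 against 103 FPKM in WT and the library labelled Sema6D-/-) and S100a9 (269 against 79.3), and the granule genes Ngp (-1.80) and Ltf (-1.6) were among them. Macrophages also express S100a8, S100a9 and Chil3.

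The PPARg list had 1 higher and 3 lower of 25 measured members without LPS and a median of -0.23 (percentile 0.07), with Cd36, Pparg and Hilpda, a lipid droplet protein (-1.04), lower and Acsl1 (1.81) higher. Fabp4 had -0.29. LXR targets had a median of -0.38 (percentile 0.03) with 0 of 14 past 2-fold, among them Apoe, the main apolipoprotein of macrophages (1451 against 2829 FPKM, -0.96), Pltp (-0.92) and the cholesterol exporter Abca1 (-0.83). Alternative activation had 0 higher and 4 lower of 20 measured (median -0.33, below all random lists), namely Chil3, Mrc1, Il10 and the folate receptor Folr2 (-1.04). NRF2 targets had a median of -0.37, below all random lists, including catalase, Cat (-1.01), and Hmox1, heme oxygenase (-0.74). Immediate early genes had 0 higher and 4 lower of 19 (median -0.55, below all random lists), with Fosl1 (-2.35), Myc (-1.27), Fosb (-1.15) and Egr1 (-1.08). Neutrophil markers were lower in the same comparison (median -1.0), and with 1 library per group it is not shown whether these lists are linked to them.

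Interferon-stimulated genes were at least 2-fold higher without LPS for 23 of 40 members and lower for 0 (median 1.08), NF-kB genes for 8 and 0 of 24 (0.50) and MHC class II and dendritic cell markers for 5 and 1 of 14 (0.71), all above all random lists. Gbp5 had 2.31, Traf1 2.01, Itgax, the integrin CD11c, 2.74 and Cd74, the invariant chain, 1.38. Cytokines and chemokines had 4 higher and 3 lower of 29 (median 0.43, above all random lists), with Ccl5 (2.05) and Il1b (1.61) higher and Ccl7 (-2.31) and Ccl2 (-1.37) lower. Tnf had 0.78 [0.68, 0.88], while Il6, at 27 and 22 fragments, had 0.76 [-0.10, 1.64], not detectable at this depth. Nos2 had 0.90 and Il12b 0.99. Cholesterol synthesis genes had 2 higher and 0 lower of 22 (median 0.53, above all random lists), among them Stard4, a sterol carrier (1.24). Arg1, the arginine-degrading enzyme, was at 25 fragments in WT and 3 in the library labelled Sema6D-/- (-2.60 [-4.96, -0.88]).

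Smaller shifts that stood apart without LPS were fatty acid oxidation (median 0.24 over 27 members, percentile 99.9, 0 higher and 1 lower, Acadl -1.02), semaphorins and plexins (0.30, percentile 99.8, Plxnd1 1.51 and Sema4d 1.09), the ATF4 list (-0.16), cell cycle (-0.10) and macrophage identity (-0.16). By the mean, fatty acid oxidation (0.12), semaphorins and plexins (0.29) and the ATF4 list (-0.14) did not stand apart, nor did semaphorins and plexins with unmeasured members kept (0.01). Macrophage identity had a mean of 0.05, opposite in sign to its median, with Cx3cr1 at 2.92, the LPS co-receptor Cd14 at 1.13 and the integrin Itgam at -0.84. Plxna1 was higher at 57.1 against 39.8 FPKM (0.52 [0.48, 0.56]) and Mtor had 0.22. mTOR signalling (-0.02), fatty acid synthesis (-0.05), glycolysis (0.10), oxidative phosphorylation (0.10) and lysosome genes (-0.00, mean 0.05) did not stand apart. In all 259 of 10322 genes were at least 2-fold higher and 226 lower. Among protein-coding genes 221 of 9991 were higher and 171 lower, and without X and Y genes the counts were 250 and 221.

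With LPS the library labelled Sema6D-/- had higher inflammatory cytokines than WT, while Il10, Pparg, Cd36, Mrc1 and Chil3 were lower, as without LPS. Tnf measured 1794 against 357 FPKM (2.33 [2.30, 2.36]), Il6 732 against 169 (2.12 [2.06, 2.17]), Il1b 1110.3 against 177 (2.65 [2.60, 2.69]), Il12b 78.3 against 26.0 (1.59 [1.48, 1.71]) and Nos2 449 against 128 (1.81 [1.78, 1.84]). Il10 was lower at 39.1 against 96.7 FPKM (-1.31 [-1.43, -1.18]). Of 29 cytokines and chemokines 18 were at least 2-fold higher and 1 lower (median 1.37, above all random lists), with Il1a at 3.25, Cxcl2 at 2.57 and Cxcl1 at 2.49. Neutrophil markers were again lower for 9 of 19 members (median -0.99, below all random lists), among them S100a9 (-1.89 [-2.02, -1.77]). Il4i1, a secreted amino acid oxidase that also ranked high among protein-coding genes, had 3.0.

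Pparg stood at 2.81 against 7.11 FPKM with LPS (-1.34 [-1.71, -1.0]), Cd36 at 27.6 against 263 (-3.25 [-3.33, -3.17]), Mrc1 at 21.3 against 51.4 (-1.27 [-1.35, -1.20]) and Chil3 at 21.6 against 61 (-1.49 [-1.65, -1.35]). The PPARg list had 2 higher and 4 lower of 25 (median -0.27, percentile 0.01), with Hilpda (-1.54) lower and Acsl1 (1.55) and the fatty acid carrier Fabp3 (1.41) higher, while Fabp4 had 0.48. LXR targets had 1 higher and 4 lower of 14 (median -0.75, below all random lists), with the desaturase Scd2 (-1.76), Arl4c (-1.27), Pltp (-1.09) and Abca1 (-1.07) lower and Srebf1, a regulator of lipid synthesis (1.59), higher. Alternative activation had 2 higher and 5 lower of 20 (median -0.20, percentile 0.470), with Cd200r1, an inhibitory receptor (-1.34), lower and the chemokine Ccl22 (2.15) higher, and it did not stand apart by its mean (-0.22) or with unmeasured members kept (-0.04). NRF2 targets had a median of -0.24 (percentile 0.05), including Nqo1 (-0.79), and did not stand apart by their mean (-0.22). Neutrophil markers were lower in this comparison too (median -0.99), with the same limit. Arg1 was at 11 fragments in WT and listed at 0 in the library labelled Sema6D-/-.

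Interferon-stimulated genes were at least 2-fold higher with LPS for 5 of 40 members and lower for 0 (median 0.56), NF-kB genes for 7 and 0 of 24 (0.67), MHC class II and dendritic cell markers for 7 and 0 of 14 (0.84) and cholesterol synthesis genes for 2 and 0 of 22 (0.59), all above all random lists. Xaf1 had 2.35, Tnfaip3, a brake on NF-kB, 1.41, H2-Aa 1.97 and Itgax 3.68. Glycolysis stood apart (1 higher and 0 lower of 20, median 0.33, percentile 99.2), with the phosphofructokinase genes Pfkm (1.36) and Pfkl (0.84). Macrophage identity had a median of -0.08 (percentile 0.790) and a mean of the other sign, 0.02, and did not stand apart among unmatched random lists, with Mertk, a receptor for apoptotic cells, at 1.97 and Itgam at -1.02. Fatty acid oxidation (-0.03), fatty acid synthesis (-0.14), mTOR signalling (-0.05), cell cycle (-0.07) and immediate early genes (-0.08) did not stand apart. Neither did semaphorins (0.13), oxidative phosphorylation (0.17), the ATF4 list (0.14) or lysosome genes (0.15), whose medians became -0.10, -0.06, -0.07 and -0.08 after rescaling to a common total. Plxna1 (0.13) became -0.10 and Mtor (0.16) -0.03 under the same rescaling.

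With LPS 311 of 10078 genes were at least 2-fold higher in the library labelled Sema6D-/- and 320 lower, and among protein-coding genes 276 of 9790 were higher and 270 lower. Without X and Y genes the counts were 303 and 310. Rescaling to a common total gave 188 higher and 410 lower.

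**Figure D2:**
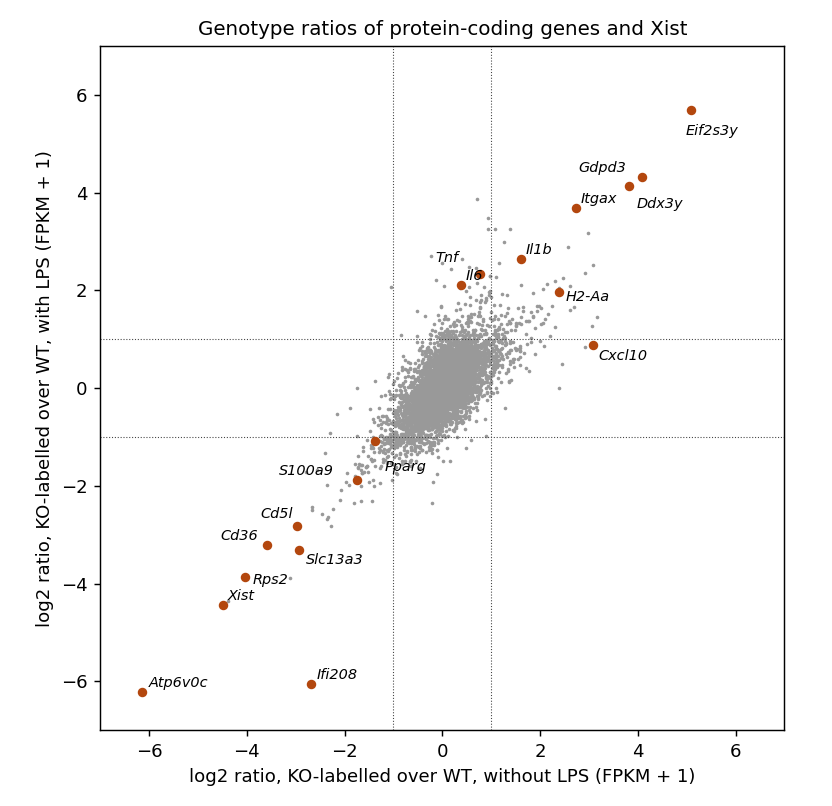
Log2 ratio of the library labelled Sema6D-/- to WT without LPS (horizontal) and with LPS (vertical) for 10291 protein-coding genes and Xist, 1 point per gene, with dotted lines at 2-fold. Of the protein-coding genes 216 were at least 2-fold apart the same way in both, such as Cd36 (-3.59 and -3.20) and Itgax (2.74 and 3.68), while Cxcl10 (3.09 and 0.88) and Il1a (0.94 and 3.25) lie off it.

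The genotype differences recurred between the comparisons without and with LPS, which share no library but share the sex-linked split, so a difference of sex, animal or culture recurs as well. Of 9720 genes tested in both, 108 were at least 2-fold higher in both libraries labelled Sema6D-/-, against 6.05 expected of independent lists, 131 were lower in both, against 5.60, and 11 went opposite ways, against 11.9. The numbers expected of independent lists are not the numbers expected without a genotype effect. Across genes the ratios correlated at r = 0.51 and rho = 0.59. The higher genes by rank included Gdpd3, a lysophospholipase D (4.09 and 4.32), Ugt1a6b, a glucuronosyltransferase (2.98 and 3.17), Itgax (2.74 and 3.68), Ly6i (3.09 and 2.53), Xaf1 (2.93 and 2.35) and the chemokine Cxcl14 (2.61 and 2.09), besides the Y-linked Eif2s3y and Ddx3y. The MHC class II genes H2-Aa (2.38 and 1.97), H2-Eb1 (2.06 and 2.02) and H2-Ab1 (1.86 and 1.94) followed. The lower genes included Cd36 (-3.59 and -3.20), the dicarboxylate transporter Slc13a3 (-2.94 and -3.30), the macrophage-secreted scavenger protein Cd5l (-2.98 and -2.82), Fcrls (-2.08 and -2.29) and the ubiquitin hydrolase Uchl1 (-2.66 and -2.44). Atp6v0c, a subunit of the lysosomal proton pump (-6.15 and -6.22), and the ribosomal genes Rpl3 (-4.39 and -4.36) and Rps2 (-4.03 and -3.86) also ranked here. Rpl3, Rps2, Hmga1, Hmga1b, Kpna2 and Eif3j2 share much of their sequence with other genes, so their values are uncertain.

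**Figure D3:**
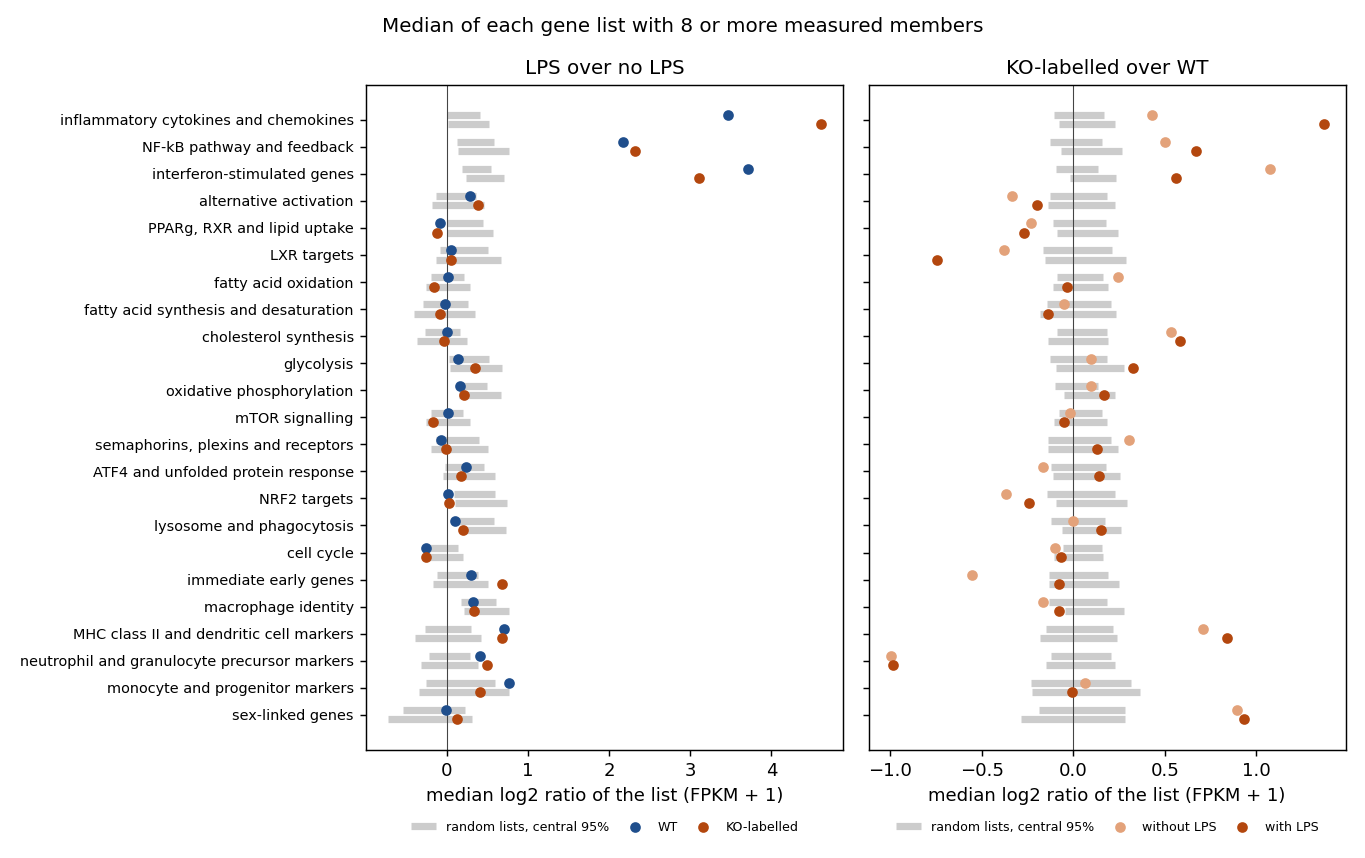
Median log2 ratio of 23 gene lists with at least 8 measured members, for LPS over no LPS in each genotype (left) and for the library labelled Sema6D-/- over WT without and with LPS (right), with grey bars for the central 95% of 10000 random lists. Neutrophil markers (-1.0 and -0.99) lay farthest below 0 in the right panel, and cytokines (4.62) farthest above 0 for LPS in the libraries labelled Sema6D-/-.

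Markers of other cell types were checked in the same way. Neutrophil markers had 2 of 19 members at least 2-fold higher with LPS in WT and 4 in the libraries labelled Sema6D-/-, with 0 lower in either. Their medians of 0.42 and 0.50 stood apart, but became -0.04 and -0.25 after rescaling to a common total and did not stand apart by their means (0.41 and 0.60), with Lcn2, a siderophore-binding protein that macrophages also make (1.15 and 1.96). Monocyte and progenitor markers, 9 measured, had LPS medians of 0.76, which stood apart, and 0.42, the latter -0.10 after rescaling to a common total, and genotype medians of 0.06 and -0.01 that did not, with the monocyte gene Ly6c2 at 0.89 and 0.88. Lymphocyte markers had 4 of 23 measured, and none of their medians stood apart (-0.14 and 0.04 for LPS, -0.20 and -0.01 for genotype). Cd79b, a B-cell receptor chain, was lower in both genotype comparisons (-1.67 and -2.31). Erythroid and megakaryocyte markers had 5 of 19 measured and did not stand apart (0.08 and 0.48 for LPS, turned to -0.47 and -0.10 by rescaling to a common total, and 0.12 and 0.33 for genotype). Mast cell markers rested on 2 measured genes, mainly the histidine decarboxylase Hdc (2.79 and 3.96), with LPS medians of 1.65 and 2.14 that stood apart and genotype medians of -0.31 and 0.19 that did not. Stromal markers rested on 4 genes of 18, including Pdgfrb at 4.31 FPKM or less, with LPS medians of 0.73 and 1.14 and a genotype median with LPS of 0.59 that stood apart, and 0.18 without LPS that did not. With unmeasured members kept no stromal median stood apart, and the mast cell median in WT did not against unmatched random lists. None of these lists stood apart in the difference of the responses, with medians of 0.03 for neutrophil, -0.00 for monocyte, 0.19 for lymphocyte, 0.21 for erythroid, 0.50 for mast cell and 0.30 for stromal markers. The same held for macrophage identity (0.00, mean -0.03), MHC class II and dendritic cell markers (-0.01, mean 0.13) and sex-linked genes (0.07).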

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

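The tests on sex chromosomes, on sex-dependent expression, on the DNA near Sema6d, on members with few shared windows and on scaling were chosen only after the results were seen, and the counting-error tests and the share of genes with near-identical copies were chosen before. No biological explanation was tested, and the genotype that the design names stays open for every pattern.

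The LPS responses and the genotype ratios of 589 genes, named genes and measured list members, were examined. Of these genes 6 went in opposite directions between groups in 1 of the 2 measures, each side at least 1.5-fold. The medians of the gene lists were examined by the same rule, and none was flagged. With 1 library per group these differences were not tested. The LPS response of Cytip, a regulator of leukocyte adhesion, was -0.94 in WT and 1.16 in the libraries labelled Sema6D-/-. For 5 genes the ratio of the library labelled Sema6D-/- to WT had opposite signs without and with LPS. It was 0.89 and -0.97 for Cxcr4, -0.81 and 0.67 for Nfkbiz, an NF-kB regulator, and -0.85 and 1.08 for Rgs1, a brake on chemokine receptors. It was -1.05 and 2.08 for the MHC class I gene H2-Q6, of a family with closely similar members, from 29, 38, 1 and 177 fragments in WT without and with LPS and in the other genotype in the same order. It was 0.87 and -0.62 for Ndufs5, a subunit of mitochondrial complex I, from 45, 4, 65 and 0 fragments in that order.

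The first pattern is the set of 216 protein-coding genes at least 2-fold apart between genotypes in both stimulation states. Genes on the X and Y chromosomes made up 3.70% of them (8 genes), which argues against sex chromosomes as the main source, and simulated counting error alone gave 0% of the observed number, which argues against counting error. The 100 measured genes nearest Sema6d held 5 of them (2.31%). Over 7505 windows of 100 neighbouring genes the median was 2, and 12.5% held at least as many as 5. A window of 100 genes could not have held most of the 216, so this count could not decide on strain variants as the main source. It shows only that nearly all of these genes lay outside that window, and variants elsewhere were not tested. Sex-dependent expression of genes on other chromosomes may contribute, and it cannot be told apart from genotype, because 0 genotypes had libraries of both sexes. Differences between animals or cultures, and an exchange of the genotype labels, stay open as well and were not tested.

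The second pattern is the 17 protein-coding genes at 5 FPKM or more and at least 4-fold lower in both libraries labelled Sema6D-/-. Of the 16 with a sequence, 37.5% (Eif3j2, Hmga1, Hmga1b, Kpna2, Rpl3 and Rps2) had at least 50% of their 50-base windows in a transcript of another gene, against a median of 0 in 1000 matched sets, the central 95% of which reached 12.5%. Reads shared with near-identical copies are therefore a candidate explanation for these members. The windows were the same for all 4 libraries, so this would also need reads to be assigned differently between the genotypes, which was not tested. Shared reads are argued against for 7 members with under 5% of windows shared, namely Cd36, Cd5l, Fcrls, Lrmda, Slc13a3, Slc35g1 and Uchl1. Atp6v0c (12.2%), Cd55 (10.9%) and Ifi208 (25.9%) lie between. Strain variants in the DNA that flanks Sema6d are argued against as a shared source, since 0% of members were among the 100 measured genes nearest Sema6d.

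The third pattern is the larger LPS response in the libraries labelled Sema6D-/- on the deposited scale. For induced genes the share with the larger response was 68.1% as deposited, 64.4% with pairs centred on the median and 48.75% after rescaling to a common total, so scaling between libraries could account for it and cannot be told apart. Only the common total removed it. That total includes the induced genes themselves, so a larger induction in a library lowers its own rescaled values. For repressed genes the share was 83.4% as deposited. These rescalings shift every response in the libraries labelled Sema6D-/- further down than in WT, which cannot lower the share for a fixed set of genes. They also changed the set, from 675 genes to 920 (86.1%) and 2194 (89.9%). They were therefore no test of whether scaling accounts for the share of repressed genes. With the gene sets as deposited, a constant was added to every difference of the log2 responses. The larger of the shares of induced and of repressed genes was never below 76.2% (reached at a constant of 0.11). A constant that lowers 1 share raises the other, so this outcome was fixed by the deposited shares of 68.1% and 83.4%. It is no separate test, and says only that no single constant accounts for both shares at once. Counting error is argued against because, among the 2573 protein-coding genes with the highest mean values, the share was 64.1% of 579 induced and 90.0% of 40 repressed genes, and 61.9% of 370 and 92.4% of 118 when as many genes were taken by their values without LPS alone.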

How the results depend on the processing

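The restrictions to protein-coding genes and to genes outside X and Y, and the 1-transcript setting for results other than the pair counts, were chosen only after the data were seen. No paired analysis was run, because each comparison held a single pair of libraries. An additive model across both genotypes and states, which would pair the genotypes by state, was not fitted. No leave-one-out setting or replicate block was run because each group was 1 library. Of 142 recomputed counts 88 stayed within 1.5 times the deposited-scale value. Of 1080 recomputed list values 1030 stayed on the same side of the percentile limits, 29 moved inside them, 19 moved outside and 2 reversed. Centring on the median or on the trimmed mean takes the same value off every gene. It could not move a list among its random lists, so list values under these settings stayed by construction. Of 1260 recomputed gene values 1000 belonged to genes at least 2-fold apart, of which 1000 kept their sign and 984 stayed at least 2-fold apart. Most of these genes were named because their ratios ranked highest or lowest in these libraries. Their signs were therefore unlikely to turn, and these counts say little about other genes. Depth limits genes with few fragments, such as Sema6d and Arg1, and pseudocounts weigh on them most.

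Other size rules gave other counts by construction. At 1.5-fold the LPS comparison in WT gave 1793 genes higher and 1441 lower, that in the libraries labelled Sema6D-/- 2288 and 2093, genotype without LPS 718 and 601, genotype with LPS 1009 and 797, and the difference of responses 595 and 610. At 4-fold the same order gave 420 and 78, 537 and 163, 53 and 62, 58 and 57, and 58 and 48. Genes apart in both states were 398 higher and 355 lower at 1.5-fold and 16 and 24 at 4-fold.

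A pseudocount of 0.1 FPKM weighs low values more and gave 892 genes lower with LPS in WT and 1443 in the libraries labelled Sema6D-/-, 406 higher and 359 lower by genotype without LPS, 492 lower with LPS, 294 and 363 for the difference, and 165 and 204 in both states. Pearson's r of the responses was then 0.70. A pseudocount of 5 FPKM weighs low values less and gave 188 and 293 genes lower with LPS, 130 higher and 104 lower by genotype without LPS, 174 and 126 with LPS, 116 and 68 for the difference, and 52 and 50 in both states.

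Rescaling to a common total gave 713 genes higher and 1502 lower with LPS in WT, 745 and 3008 in the libraries labelled Sema6D-/-, 188 higher by genotype with LPS, and 123 and 222 for the difference. The cause was not tested. Genes with 1 transcript only, which are fewer, gave 963 higher with LPS in the libraries labelled Sema6D-/-, 71 higher and 84 lower in both states, and r = 0.71. Protein-coding genes, again fewer, gave 79 lower for the difference and r = 0.93. Spearman's rho without a filter, which adds genes near 0, was 0.74.

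With random lists not matched on expression, which changes the random lists and not the medians, these medians moved outside the percentile limits: alternative activation for LPS in both genotypes (0.29 and 0.38), immediate early genes for LPS in WT (0.30) and macrophage identity for LPS in both (0.32 and 0.34). Moving inside were the PPARg list (-0.0766 and -0.12) and NRF2 targets (0.0139 and 0.0277) for LPS in both, lysosome (0.11), mast cell (1.65) and stromal (0.73) markers for LPS in WT, and macrophage identity by genotype with LPS (-0.0800).

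With the mean in place of the median, macrophage identity reversed, to 0.0550 by genotype without LPS and 0.0228 with LPS; the cause was not tested here or for the other list means. Moving outside the limits were alternative activation for LPS in the libraries labelled Sema6D-/- (0.76), LXR targets for LPS in both genotypes (-0.15 and -0.31), oxidative phosphorylation for LPS in WT (0.18), mTOR signalling for LPS in both (-0.26 and -0.28) and macrophage identity for LPS in both (0.12 and 0.0912). Moving inside for LPS were cell cycle in WT (-0.18), neutrophil markers in both (0.41 and 0.60), and the PPARg list (-0.0658) and NRF2 targets (0.13) in the libraries labelled Sema6D-/-. Moving inside by genotype without LPS were fatty acid oxidation (0.12), semaphorins (0.29) and the ATF4 list (-0.14), and with LPS alternative activation (-0.22), NRF2 targets (-0.22) and stromal markers (0.48). Glycolysis (0.20) and immediate early genes (0.31) moved inside for the difference.

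With unmeasured members kept, which adds genes near 0, alternative activation moved outside for LPS in both genotypes (0.22 and 0.27), fatty acid synthesis by genotype with LPS (-0.13) and mast cell markers by genotype without LPS (-0.0726). Moving inside were alternative activation by genotype with LPS (-0.0429), semaphorins without LPS (0.0136), stromal markers for LPS in both (0.0165 and 0.027) and by genotype with LPS (0.0145), and sex-linked genes by genotype without and with LPS (0 and 0). The mast cell median for LPS in WT moved inside with a pseudocount of 0.1 FPKM (2.06), the stromal difference moved outside with 5 FPKM (0.23), and the median of the gene list: sex-linked genes, WT LPS against WT non, moved outside after rescaling to a common total (-0.0946). The cause was not tested.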

Other observations

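No explanation is offered in this part, and the choice of what to report here was made only after the data were seen. Clec4e, a C-type lectin that senses mycobacterial glycolipid, measured 318 against 34.6 FPKM in WT without LPS (3.16) and 2002.5 against 732 with LPS (1.45). Gpr84, a receptor for medium-chain fatty acids, had 3.05 and 1.27, and the haptoglobin gene Hp had 2.70 and 1.66. Epas1, which encodes a hypoxia-inducible factor, had 2.61 and 1.60. Thbs1, the matrix glycoprotein thrombospondin, was lower in both states (-2.80 and -1.71), as were the adaptor gene Nck2 (-2.57 and -1.68) and Mmp27 (-2.40 and -1.32).

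Genes of chromosome 17, which carries the mouse MHC, were frequent among protein-coding genes at least 2-fold apart in both genotype comparisons. There were 26 of 497 measured genes on chromosome 17 (5.23%), against 0.685 to 3.95% on the other autosomes and 1.40% on X, while all 4 measured Y genes were apart. Chromosome 17 was singled out after looking over 21 chromosomes, so this is a value only. Its genes included H2-Aa, H2-Ab1, H2-Eb1 and H2-T24 (2.39 and 2.05), which were higher, and Atp6v0c, Rps2 and Hmga1 (-2.29 and -2.82), which were lower, in the libraries labelled Sema6D-/-.

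Small RNAs, which stranded mRNA libraries do not measure well, took 5.72% and 3.88% of the summed FPKM in WT without and with LPS and 3.94% and 2.37% in the libraries labelled Sema6D-/-. The 10 transcripts with the highest values took 16.2 to 18.8% of the summed FPKM in the 4 libraries.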
